A study of Homo sapiens with 9 samples.

How the data were processed

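Total RNA of HaCaT cells, an established immortalized human keratinocyte line, was sequenced in 9 libraries. The labels place 3 libraries in a sorted subpopulation named BD, 3 in a sorted subpopulation named NBD and 3 in the cell line, named control. The 2 names are not spelled out in the labels and are used here as given. The subpopulations were sorted by fluorescence, and stranded, rRNA-depleted, paired-end libraries were built from total RNA, per the labels' protocols. The protocol names 2 micro-scale RNA kits, and which library came from which is not given in the sources used here.

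The values analysed are read counts per gene, as deposited by the authors, with no normalization. Reads were processed with FastQC 0.74, Trimmomatic 0.39, STAR 2.7.11b and featureCounts against GRCh38, per the submitters' processing notes. The annotation release, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. Genes that overlap, have an antisense partner or have near-identical copies therefore have uncertain counts. Each library lists 78899 gene IDs, of which 39344 had a count in at least 1 library. A symbol was found for 61458 IDs in a gene name table and for 54 more in GENCODE 29, an annotation of GRCh38, which also gave the type and coordinates of 57338 IDs. IDs with a symbol held 99.8% of all counts.

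Total counts ranged from 17128797 to 29512856 per library. The tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 16921, and libraries were scaled by TMM. The filter was applied anew when a library was left out, and 17755 genes were tested without control replicate 3. One quasi-likelihood fit held all 9 libraries with a term per group and no other covariate, leaving 6 residual degrees of freedom. The comparisons were BD against NBD, BD against control, NBD against control, and the mean of BD and NBD against control. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Levels are normalised CPM, counts relative to the TMM-scaled library total, and are given as mean ± SD with n = 3. Log2 fold changes are given ± the standard error.

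Before the data were examined, 33 gene lists were fixed on keratinocyte biology, growth, stress, signalling and other cell types the samples could hold. Of these, 29 had at least 5 tested members and were tested with camera on the counts with a preset inter-gene correlation of 0.01, with adjustment over the lists. An estimated correlation was the alternative. Fixed at the same time was a rule for the genes named: per direction the 8 largest changes (5 for both subpopulations together) among called protein-coding genes with at least 5 CPM in the higher group and groups that do not overlap, up to 4 called members of each list, and 12 fixed genes. Without control replicate 3 the same rule was applied again. Genes outside the rule are said to be chosen after their values were seen.

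Alternatives fixed before the data were examined were other size factors, no filter, a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with limma 3.58.1, the replicate number as a block, a log2 fold change of at least 1, protein-coding genes alone, the 6 libraries of the groups compared alone, and leaving out each library in turn. Control replicate 3 as the only control library, in a fit that takes its spread from the other groups, removal of both mitochondrial rRNA genes, and removal of a trend with transcript length were chosen after seeing the data.

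The edgeR test was tested on simulated counts with 66 or 67 genes changed per fold size. The changed genes were drawn from those with a mean log2 CPM above 2, and the spread came from the fit to all 9 libraries. At a 2-fold change the test recovered 11.9%, 17.9% and 10.4% of changed genes for BD against NBD, BD against control and NBD against control. At a 4-fold change it recovered 87.9%, 90.9% and 86.4%, and at a 1.5-fold change 0%, with 4, 4 and 2 false calls. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes of the Y chromosome and XIST were left out of the named genes.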

Results

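RNA was sequenced from HaCaT keratinocytes to compare sorted subpopulations, with the stated interest in cell states linked to progenitors. The 3 BD libraries held 27678024, 25754757 and 28948743 counts, the 3 NBD libraries 26345128, 25862752 and 29512856, and the 3 libraries of the cell line labelled control 18054999, 17128797 and 25782938. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

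Mitochondrial rRNA took 20.2 ± 2.61% of counts in BD and 27.7 ± 1.09% in NBD (SD, n = 3 each), against 12.3%, 11.9% and 20.7% in the control libraries. Small nucleolar RNAs, which guide rRNA processing and modification, took 0.135 ± 0.00951% in BD and 0.644 ± 0.0905% in NBD, against 1.07%, 1.19% and 0.509% in the control libraries. In BD and NBD, 0.123 ± 0.00975% and 0.625 ± 0.0880% of counts were from SNORD3A alone, chosen after its values were seen, and 0.0121 ± 0.000695% and 0.0193 ± 0.00320% from all other small nucleolar RNA genes. The 13 mRNAs encoded by the mitochondrial genome took 0.486 ± 0.0681% in BD, 0.865 ± 0.0280% in NBD, and 0.317%, 0.314% and 0.538% in the control libraries. These shares were not tested. For a single library, Wilson 95% intervals spanned at most 0.0342 percentage points for mitochondrial rRNA, 0.0103 for small nucleolar RNA and 0.00725 for mitochondrial mRNA, and cover counting error only.

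The control libraries were not alike. KRT15, a keratin of basal and hair follicle stem cells (GRCh38 chromosome 17, 41513743 to 41522529), stood at 27.1 and 27.3 CPM in control replicates 1 and 2, at 442 CPM in control replicate 3, and between 285 and 446 CPM in the 6 sorted libraries. LCN2, an iron-binding defence protein, stood at 1.02 and 1.23 CPM in control replicates 1 and 2 and at 811 CPM or more in each of the other 7 libraries. ADD2, a cytoskeletal adducin, stood at 61.2 and 59.0 CPM in these 2 libraries, at 1.61 CPM in NBD replicate 2 and at 0 in the other 6. The receptor gene TLR2 had 0 counts in both, where 3 counts would be 0.153 and 0.168 CPM, and 12.1 to 18.9 CPM in the other 7. LCN2, ADD2 and TLR2 are named by the rule as applied without control replicate 3, after the values had been seen.

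Over 19807 protein-coding genes, 160 had at most 3 counts in control replicate 1 while the median of the other 8 libraries was at least 1 CPM. Control replicate 2 had 156 such genes, of which 122 were shared with control replicate 1, and the other 7 libraries had 0 to 3 each. The first principal component held 58.6% of the variance and placed control replicates 1 and 2 at 119 each, NBD replicate 2 at 1.86 and the other libraries between -49.9 and -26.6. Log2 CPM of control replicate 3 correlated across genes at r = 0.992 to 0.997 with the sorted libraries and at 0.979 and 0.980 with control replicates 1 and 2. Genes are not independent replicates.

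**Figure D1:**
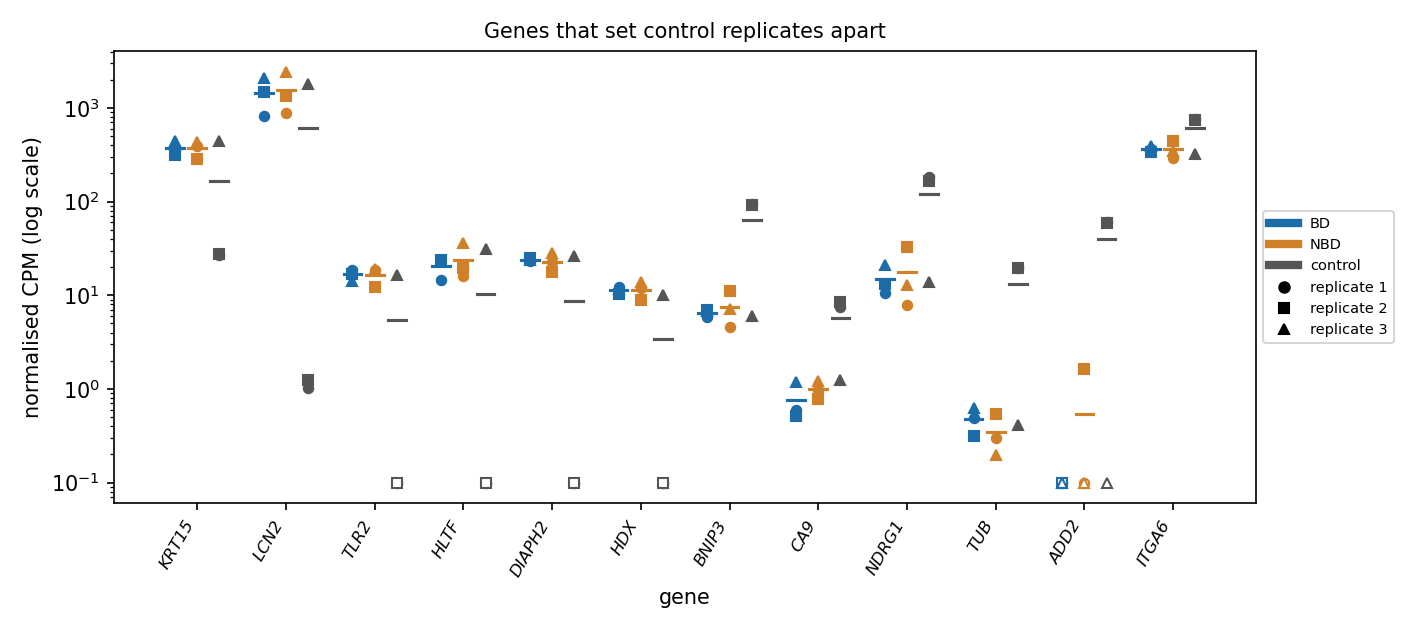
Normalised CPM on a log axis for 12 genes in each library, with colour for the group, symbol for the replicate a line at the group mean, and open symbols at 0.1 for values under 0.1 CPM. Control replicates 1 and 2 lie apart from control replicate 3, for example at 27.1, 27.3 and 442 CPM for KRT15.

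Against NBD, BD libraries held a lower level of mRNA from the mitochondrial genome, relative to the library total. Which of the 2 RNA kits gave which library is not stated in the sources used here, so a kit difference was not excluded. MT-ND4, a subunit of respiratory complex I (mitochondrial genome, 10760 to 12137), fell from 260 ± 53.3 CPM in NBD to 73.3 ± 8.34 CPM in BD (SD, n = 3), a log2 fold change of -1.83 ± 0.20. MT-ATP6, a subunit of ATP synthase (8527 to 9207), fell from 135 ± 43.7 to 33.0 ± 3.64 CPM, a log2 fold change of -2.04 ± 0.23. MT-CYB, cytochrome b of complex III (14747 to 15887), fell from 221 ± 29.4 to 72.3 ± 5.69 CPM, a log2 fold change of -1.61 ± 0.20. Control levels were 122 ± 14.2, 49.5 ± 4.61 and 111 ± 23.4 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.0320 for MT-ND4 and MT-ATP6 and 0.0457 for MT-CYB. Each gene was lower in 3 of 3 BD libraries than in any NBD library. The calls rest on these same libraries, so this separation adds no support to them.

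These were the 3 genes called of 16921, all lower in BD. An unadjusted p under 0.05 was reached by 991 genes, where 846 would be reached by chance, and DESeq2 called 58, 9 higher and 49 lower. The log2 fold changes ran from -1.95 to -1.65 for MT-ND4, from -2.18 to -1.74 for MT-ATP6 and from -1.68 to -1.49 for MT-CYB over 18 alternatives, while the calls came and went. With the replicate number as a block edgeR called 0 genes. It also called 0 without BD replicate 1, 2 or 3, NBD replicate 2 or 3, or control replicate 1, and 16 without control replicate 3. Over these alternatives adjusted p ran from 3.4e-13 to 0.404 for MT-ND4, from 2.6e-12 to 0.404 for MT-ATP6 and from 3.8e-10 to 0.459 for MT-CYB. Nuclear copies of mitochondrial genes can share reads with them, and the 3 that were tested, chosen after their values were seen, were called by DESeq2 and not by edgeR with all libraries, MTATP6P1 at -2.20 ± 0.36, MTND2P28 at -1.65 ± 0.35 and MTCO1P12 at -1.19 ± 0.27. Without control replicate 3 edgeR called MTATP6P1 (adjusted p = 0.0395). Over the alternatives adjusted p ran from 6.9e-06, 0.00399 and 0.0152 to 1.00 for the 3.

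The list of mitochondrially encoded respiratory chain genes fell, with all 13 members below 0 and a median log2 fold change of -1.80 (camera, adjusted p = 2.11e-65, and adjusted p = 0.00686 with an estimated correlation). Over all genes 3 members were called, and adjusted over the list alone 12 were. Without control replicate 3 these counts were 7 and 13. The ribosomal RNAs of the same genome were not called, MT-RNR1 at -0.36 ± 0.29 and MT-RNR2 at -0.61 ± 0.41, both given after their values were seen. The libraries were rRNA-depleted, so these 2 values also depend on what depletion left. All 10 mitochondrial tRNA genes tested, also given after their values were seen, were below 0, at a median of -2.34. By edgeR 7 of them had an unadjusted p under 0.05 and 0 were called, and DESeq2 called MT-TV, MT-TE, MT-TP and MT-TC lower. The abundant nuclear and small non-coding RNA list was called lower, with 7 of 8 members below 0 and a median of -0.57 (camera, adjusted p = 9.2e-04, and adjusted p = 0.107 with an estimated correlation). In it SNHG1, a small nucleolar RNA host gene, was at -1.04 ± 0.22, NEAT1, the scaffold of paraspeckles, at -1.89 ± 0.49 and MALAT1 at -1.01 ± 0.31, named after their values were seen. By edgeR 0 of its members were called over all genes and 3 adjusted over the list alone, and DESeq2 called SNHG1 and NEAT1. Over the alternatives adjusted p ran from 0.00850 for SNHG1, 1.1e-08 for NEAT1 and 0.122 for MALAT1 to 1.00 for each. The small nucleolar RNA gene SNORD3A, chosen after its values were seen, was at 1217 ± 97.6 CPM in BD and 6692 ± 1191 CPM in NBD, a log2 fold change of -2.46 ± 0.34 without a call with all libraries (edgeR, adjusted p = 0.0566). It was called by DESeq2 (4.6e-12), and by edgeR without control replicate 3 (0.00597) or with the 6 libraries of BD and NBD alone (0.0257), and over the alternatives adjusted p ran from 4.6e-12 to 0.549. SNORD3A has near-identical copies, so its count is uncertain.

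**Figure D2:**
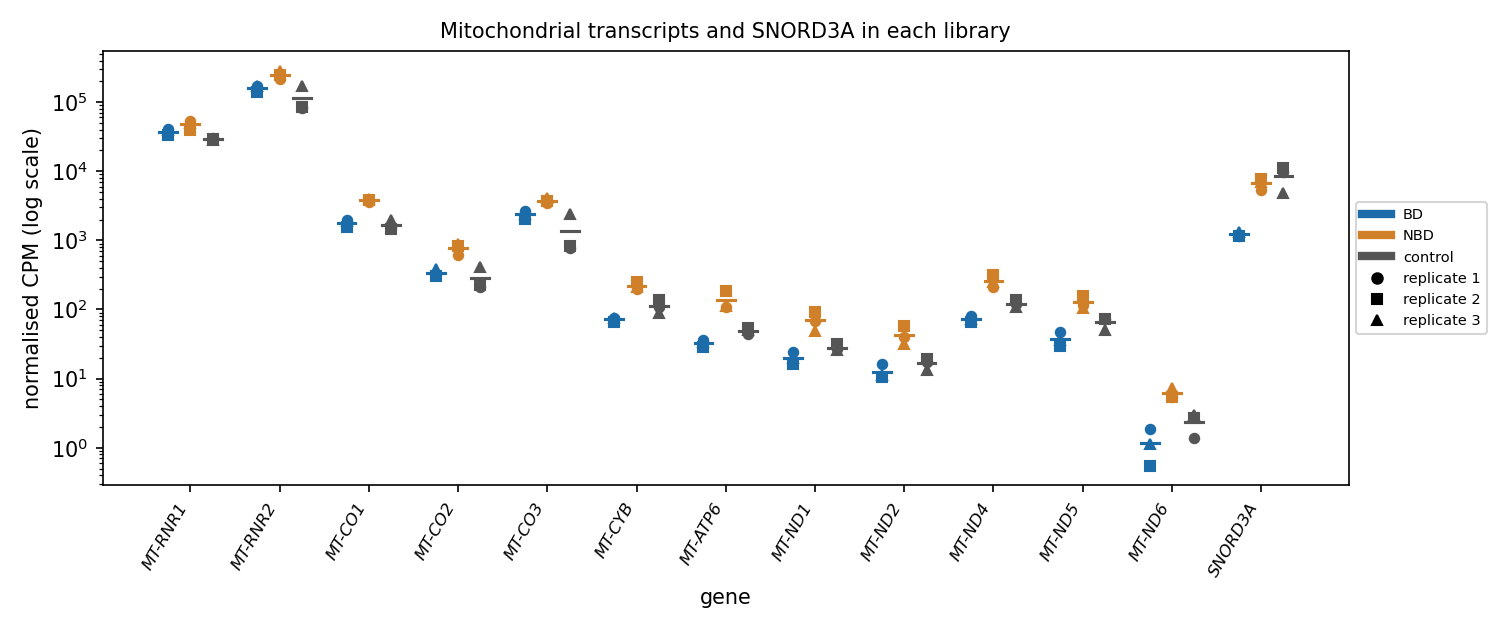
Normalised CPM on a log axis for mitochondrial transcripts and SNORD3A in each library, with colour for the group, symbol for the replicate and a line at the group mean. MT-ND4 lies at 73.3 CPM on average in BD and 260 CPM in NBD.

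The G2 and mitosis list was called lower in BD, with 24 of 29 members below 0 and a median of -0.39 (camera, adjusted p = 6.0e-09, and adjusted p = 0.767 with an estimated correlation). The kinesin KIF23 was at -0.66 ± 0.16, the centromere motor CENPE at -1.47 ± 0.43 and the proliferation marker MKI67 at -1.33 ± 0.43, none of them called by edgeR, KIF23 called by DESeq2, and the first 2 chosen after their values were seen. With no filter edgeR called CENPE and MKI67, and over the alternatives adjusted p ran from 0.0134 for KIF23, 3.1e-06 for CENPE and 4.7e-04 for MKI67 to 1.00 for each. The ribosomal protein list was called higher, with 75 of 78 members above 0 and a median of 0.29 (camera, adjusted p = 6.7e-09, and adjusted p = 0.900 with an estimated correlation). The ribosomal protein gene RPL36A, which the list does not hold and which was chosen after its values were seen, was lower at -1.05 ± 0.21, called by DESeq2 (adjusted p = 0.00162, up to 1.00 over the alternatives) and not by edgeR (0.324). Also called higher were the unfolded protein and integrated stress list at a median of 0.32 (adjusted p = 0.00727, and adjusted p = 0.767 with an estimated correlation), the nuclear-encoded respiratory chain list at 0.15 (0.0104, and adjusted p = 0.900 with an estimated correlation) and the immediate-early response list at 0.32 (0.0345, and adjusted p = 0.900 with an estimated correlation). In these 5 lists 0 members were called by edgeR over all genes and 0 adjusted over the list alone. Without control replicate 3, 6 members of the mitosis list were called lower and 1 of the stress list higher adjusted over the list alone. At an unadjusted p under 0.05, 9 members of the mitosis list were lower, and 2 of the stress list and 1 of the immediate-early list were higher. The other 22 lists were not called, at adjusted p from 0.130 to 0.990, keratinocyte layers and sorting markers among them. Of these, the mesenchymal transition, NF-kB and inflammatory cytokine, and Notch pathway lists had medians of -0.09, -0.06 and -0.03 while their tests pointed up. Without NBD replicate 3, 12 lists were called against 7. The interferon list was called as well without control replicate 3, at 0.20 (adjusted p = 0.0264, from 0.0264 to 0.900 over the alternatives, and adjusted p = 0.788 with an estimated correlation).

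Single libraries ended the calls of 4 of these lists or moved their medians. Without NBD replicate 1 all 4 calls were lost. The ribosomal protein list was then at 0.06 (camera, adjusted p = 0.461), the unfolded protein and integrated stress list at 0.18 (0.178), the immediate-early list at 0.16 (0.385) and the nuclear-encoded respiratory chain list at -0.0045 (0.973). Leaving out BD replicate 2 ended the calls of the stress list at 0.17 (0.0878) and the nuclear-encoded list at 0.02 (0.422). The immediate-early call was lost without BD replicate 3, at -0.03 (0.836), and the nuclear-encoded call without NBD replicate 2, at 0.11 (0.0779). The ribosomal protein median was 0.47 without BD replicate 1, 0.13 without BD replicate 2 and 0.59 without NBD replicate 3. The immediate-early median was 0.63 without BD replicate 1 and 0.64 without NBD replicate 3, where the nuclear-encoded median was 0.31. Over 16 alternatives adjusted p ran from 3.2e-21 to 0.900 for ribosomal protein, from 6.8e-04 to 0.767 for the stress list, from 5.8e-05 to 0.900 for immediate-early response and from 2.5e-08 to 0.973 for the nuclear-encoded list. The mitochondrially encoded list stayed called under all 16, and the mitosis list under all but the estimated correlation.

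Of the keratinocyte and sorting genes fixed in advance, 0 were called between BD and NBD by edgeR or DESeq2. The basal keratins KRT5 and KRT14 were at 0.22 ± 0.41 and -0.12 ± 0.41 on the log2 scale, KRT15 at 0.01 ± 0.86, the basal transcription factor TP63 at 0.27 ± 0.25 and the differentiation keratin KRT10 at -0.13 ± 0.28. The integrins ITGA6 and ITGB1 were at 0.01 ± 0.31 and -0.21 ± 0.20, the transferrin receptor TFRC at -0.47 ± 0.24 and the cell cycle inhibitor CDKN1A at 0.45 ± 0.42. The late differentiation gene IVL had at most 3 counts in each BD library and 0, 0.579 and 0.118 CPM in the NBD libraries, so no fold is given. Adjusted p by edgeR lay between 0.798 and 1.00 for these 9 genes and MKI67, which alone had an unadjusted p under 0.05. KRT1, a keratin of differentiating cells, had 0 counts in all libraries but NBD replicate 2, at 0.0827 CPM, and was not tested.

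**Figure D3:**
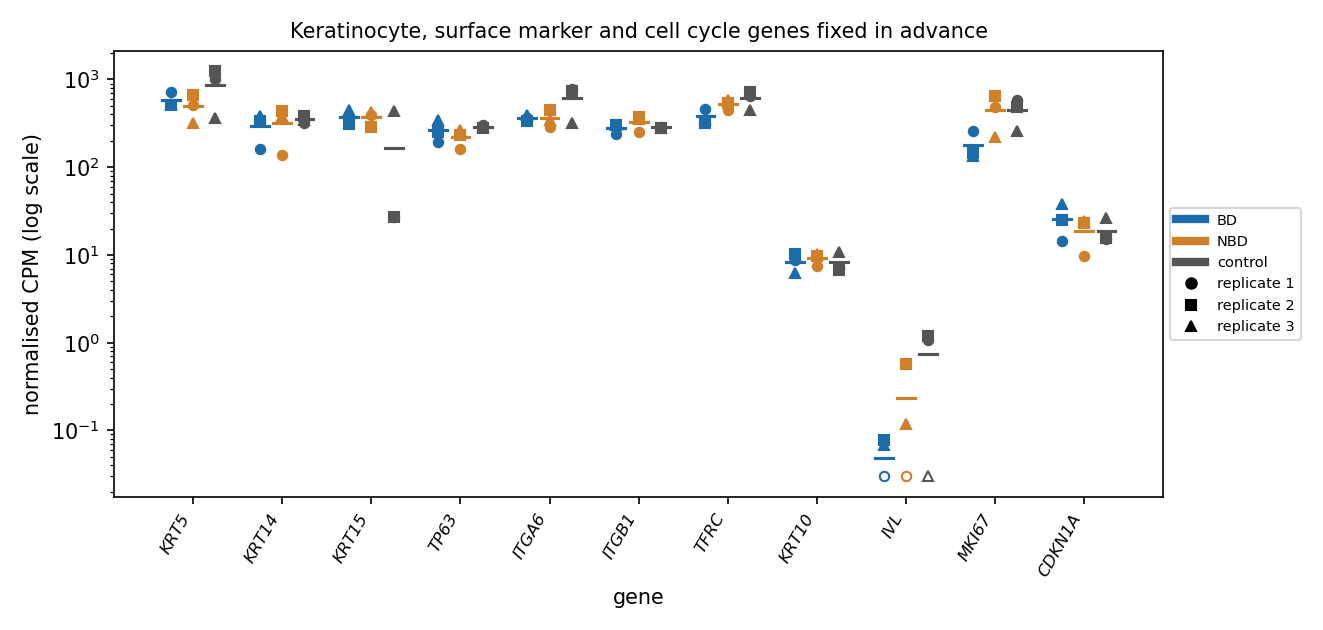
Normalised CPM on a log axis for 11 genes fixed in advance, with colour for the group, symbol for the replicate a line at the group mean, and open symbols at 0.03 for values under 0.03 CPM. BD and NBD libraries overlap for KRT5, KRT14, KRT15 and ITGA6.

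Against control, BD libraries held more interferon response transcripts and fewer hypoxia and glycolysis transcripts by the list test. All 27 tested interferon members were above 0, with a median log2 fold change of 1.01 (camera, adjusted p = 1.2e-10, and adjusted p = 0.704 with an estimated correlation), among them MX1, an antiviral GTPase, at 1.91 ± 0.63 and OAS1, a sensor of viral RNA, at 1.45 ± 0.74, both uncalled with all libraries and chosen after their values were seen. They stood at 3.30 and 3.48 without control replicate 3 (edgeR, adjusted p = 3.9e-04 and 2.5e-05, and from 7.8e-10 and 7.5e-07 to 1.00 over the alternatives). Of the interferon list 0 members were called over all genes or adjusted over the list alone, and 10 were higher at an unadjusted p under 0.05. The NF-kB and inflammatory cytokine list had all 23 members above 0 at a median of 0.87 (adjusted p = 7.1e-07, and adjusted p = 0.704 with an estimated correlation), with 0 called either way and 3 at an unadjusted p under 0.05. The hypoxia and glycolysis list was lower, at a median of -0.58 (adjusted p = 2.4e-05, and adjusted p = 0.704 with an estimated correlation), with 10 members called adjusted over the list alone, among them CA9, a carbonic anhydrase, at -2.90 ± 0.66 and BNIP3, a mitophagy receptor, at -3.30 ± 0.78, chosen after their values were seen. Both were called by DESeq2 and by edgeR without control replicate 3 (adjusted p = 3.9e-04 and 3.3e-05), with adjusted p up to 1.00 over the alternatives. The interferon, NF-kB and hypoxia medians without control replicate 3 were 1.76, 2.44 and -0.87 (camera, adjusted p = 1.7e-14, 4.4e-24 and 3.9e-10). With an estimated correlation these had adjusted p = 0.137, 0.159 and 0.229, and over the alternatives adjusted p reached 0.704 for each. In that fit edgeR called 21 interferon and 17 NF-kB members higher over all genes, and of the hypoxia list 14 lower and 2 higher. The NF-kB median was 0.44 without control replicate 1 or 2, and 1.47 with the replicate number as a block. The stress keratin and alarmin list was at -0.12 with all libraries (adjusted p = 0.823). It was called at 2.45 without control replicate 3 (0.0162, and adjusted p = 0.712 with an estimated correlation) and at -0.82 with control replicate 3 as the only control library (1.6e-04), and over the alternatives adjusted p ran up to 0.963. Each of these differences goes with the split among controls: BNIP3 stood at 95.4 and 91.3 CPM in control replicates 1 and 2, at 5.99 in control replicate 3, and at 5.87 to 6.91 CPM in BD, and OAS1 stood at 8.02, 8.19 and 81.6 CPM in the control libraries and at 80.3 to 99.5 CPM in BD.

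Of 16921 genes, 0 were called by edgeR in BD against control, while 2334 had an unadjusted p under 0.05 and DESeq2 called 167, 11 higher and 156 lower. Without control replicate 3 the count was 4317 of 17755 genes tested, 2454 higher and 1863 lower. In the fit without control replicate 3, KRT15 rose by 3.79 ± 0.28 (edgeR, adjusted p = 2.5e-05) and ITGA6 fell by 1.05 ± 0.21 (adjusted p = 0.00577), MKI67 by 1.57 ± 0.39 (adjusted p = 0.0154), TFRC by 0.86 ± 0.22 (adjusted p = 0.0166) and KRT5 by 0.94 ± 0.29 (adjusted p = 0.0361). IVL was called as well (edgeR, adjusted p = 0.0184), at 1.07 and 1.18 CPM in control replicates 1 and 2, 0 counts in control replicate 3 and at most 3 counts in each BD library. With all libraries KRT15, ITGA6, MKI67, TFRC and KRT5 were at 1.17 ± 0.87, -0.75 ± 0.31, -1.30 ± 0.43, -0.69 ± 0.24 and -0.58 ± 0.42, and 0 of the 11 fixed genes tested were called by edgeR, at adjusted p from 0.333 to 0.970. Over the alternatives the lowest adjusted p was the one given, or 1.3e-04 for MKI67 and 0.00200 for IVL, and the highest was 1.00 for each of the 6.

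The remaining lists called in BD against control were G2 and mitosis at a median of -0.42 (camera, adjusted p = 3.3e-06), immediate-early response at 0.75 (4.1e-04), unfolded protein and integrated stress at 0.35 (0.00129), mitochondrially encoded respiratory chain at -0.49 (0.00241), YAP and TEAD targets at -0.58 (0.00306), nuclear-encoded respiratory chain at 0.22 (0.00654) and surface markers used for keratinocyte sorting at -0.42 (0.0464). For these 7, adjusted p = 0.704 to 0.872 with an estimated correlation. Of the mitochondrial list 10 members were below 0 and 3 above. The summed share of its mRNAs was 0.413 to 0.547% of counts in BD, against 0.317%, 0.314% and 0.538% in the control libraries. The median therefore does not show that BD held less mitochondrial mRNA in total. Adjusted over the list alone, 3 members of the stress list and 4 of the mitochondrial list were called, and 0 of the other 5. Without control replicate 3 these were 21 higher for immediate-early response, 11 lower for mitosis and 9 lower for YAP. They were 8 higher and 1 lower for the stress list, 5 lower and 1 higher for surface markers, 4 lower and 2 higher for the mitochondrial list and 0 for the nuclear-encoded list. With all libraries the other 19 lists had adjusted p from 0.118 to 0.921. Leaving out control replicate 3 left 8 lists called. The calls of the mitochondrially encoded list at -0.53 (adjusted p = 0.192), the nuclear-encoded list at 0.35 (0.0752) and the surface markers at -0.48 (0.0752) were lost. In that fit the immediate-early list stood at 2.15 with 19 members called higher over all genes (6.2e-13, and adjusted p = 0.583 with an estimated correlation), and the YAP list at -0.88 (3.4e-04, and adjusted p = 0.712 with an estimated correlation). The immediate-early median was 0.36 without BD replicate 3 and 0.37 and 0.43 without control replicates 1 and 2. With the replicate number as a block it was 1.15. The stress median was 0.22 without control replicate 1, the YAP median -0.30 without control replicate 2, and the nuclear-encoded median 0.35 without BD replicate 1. The nuclear-encoded call was lost without BD replicate 2 at 0.10 (0.241) or control replicate 1 at 0.12 (0.105). The surface marker call was lost without BD replicate 1 at -0.45 (0.185), NBD replicate 2 at -0.42 (0.0586), NBD replicate 3 at -0.41 (0.0588) or control replicate 2 at -0.14 (0.0578). With the replicate number as a block it was lost too, at -0.32 (camera, adjusted p = 0.0974). Over 15 alternatives the lowest adjusted p of the 7 lists lay between 6.2e-13 and 0.0237 and the highest was 0.704, or 0.872 for the nuclear-encoded list. With control replicate 3 as the only control library, chosen after seeing the data and assumed to vary as the other groups do, the immediate-early list turned to -0.12 and the NF-kB list to -0.19. The calls of interferon at 0.13 (adjusted p = 0.0593), hypoxia at 0.12 (0.327), YAP at 0.17 (0.0515), nuclear-encoded respiratory chain at 0.07 (0.221) and surface markers at -0.03 (0.485) were then lost.

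NBD libraries stood above control in mitochondrial mRNA. All 13 members of the mitochondrially encoded respiratory chain list were above 0, at a median log2 fold change of 1.36 (camera, adjusted p = 8.38e-26, and adjusted p = 0.103 with an estimated correlation), and 13 were called adjusted over the list alone, against 0 by edgeR over all genes. Without control replicate 3 edgeR called 12 of them higher over all genes. MT-ATP6 was at 1.45 ± 0.23 and MT-ND4 at 1.10 ± 0.20, called by DESeq2 (adjusted p = 7.1e-05 and 0.00187) and by edgeR without control replicate 3 (0.00336 and 0.00813), with adjusted p up to 1.00 over the alternatives. The hypoxia and glycolysis list was lower, at a median of -0.67 with 8 members called adjusted over the list alone (adjusted p = 4.15e-11, and adjusted p = 0.478 with an estimated correlation). The interferon list was higher at 0.67 (1.2e-08, and adjusted p = 0.591 with an estimated correlation) and the NF-kB list at 0.92 (1.9e-05, and adjusted p = 0.647 with an estimated correlation), with 0 members of either called adjusted over the list alone and 3 and 0 higher at an unadjusted p under 0.05. These medians were 1.5 and 2.50 without control replicate 3 (camera, adjusted p = 3.3e-13 and 1.9e-24, and adjusted p = 0.112 for both with an estimated correlation), and edgeR called 21 and 15 of their members higher over all genes. Leaving out control replicates 1 and 2 in turn gave 0.41 and 0.40 for interferon and 0.37 each for NF-kB. The NF-kB median was 0.47 without NBD replicate 3, and 1.38 with the replicate number as a block. Over 15 alternatives adjusted p reached 0.649 for interferon and 0.647 for NF-kB. The stress keratin and alarmin list was at 0.53 with all libraries (adjusted p = 0.548). It was called at 1.95 without control replicate 3 (0.00810, and adjusted p = 0.688 with an estimated correlation) and at -0.58 with control replicate 3 as the only control library (0.00190), and over the alternatives adjusted p ran up to 0.862. CA9, at 0.786 to 1.22 CPM in NBD, stood at 7.46 and 8.41 CPM in control replicates 1 and 2 and at 1.24 CPM in control replicate 3, and OAS1, at 58.8 to 91.9 CPM in NBD, at 8.02, 8.19 and 81.6 CPM.

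Of 16921 genes, 0 were called by edgeR in NBD against control, while 1545 had an unadjusted p under 0.05 and DESeq2 called 30, 12 higher and 18 lower. Without control replicate 3 the count was 3228 of 17755 genes tested, 2063 higher and 1165 lower. In the fit without control replicate 3, KRT15 rose by 3.78 ± 0.28 (edgeR, adjusted p = 2.8e-05), while ITGA6 fell by 1.05 ± 0.21 (adjusted p = 0.00727) and KRT5 by 1.16 ± 0.29 (adjusted p = 0.0197). With all libraries these were 1.16 ± 0.87, -0.76 ± 0.31 and -0.81 ± 0.42, and 0 of the 11 fixed genes tested were called by edgeR, at adjusted p from 0.539 to 0.998. Over the alternatives the lowest adjusted p was the one given and the highest 1.00 for each. The metal-binding gene MT1X, named by the rule in that fit, stood at 54.6 and 56.9 CPM in control replicates 1 and 2, at 1.66 in control replicate 3 and at 2.60 to 4.85 in NBD.

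Also called in NBD against control were ribosomal protein at a median of -0.19 (camera, adjusted p = 4.2e-04), S-phase and replication at -0.12 (0.00749) and YAP and TEAD targets at -0.53 (0.00985), with adjusted p = 0.647 to 0.763 with an estimated correlation and 0 members called adjusted over the list alone. Without control replicate 3, 10 members of the YAP list and 6 of the S-phase list were called lower adjusted over the list alone, and 0 of the ribosomal protein list. With all libraries the other 22 lists had adjusted p from 0.0527 to 0.861. Without NBD replicate 1 the lists called were 15 and without NBD replicate 2 they were 12, against 7. Leaving out control replicate 3 gave 10. Immediate-early response, at 0.50 with all libraries (adjusted p = 0.0558), was then called at 1.85 (4.6e-11, and adjusted p = 0.451 with an estimated correlation), and at -0.57 with control replicate 3 as the only control library (7.7e-10). Heat shock, at -0.19 with all libraries (0.0759), was called at -0.12 (0.0386, and adjusted p = 0.688 with an estimated correlation). Over the alternatives their adjusted p ran from 4.6e-11 to 0.763 and from 0.0249 to 0.746. The ribosomal protein call was lost at 0.04 without NBD replicate 1 (0.622) and the S-phase call at -0.06 without control replicate 2 (0.0612). The YAP call was lost at -0.37 without NBD replicate 3 (0.273) and at -0.35 and -0.39 without control replicates 1 and 2 (0.0584 and 0.0575). The ribosomal median was -0.47 without NBD replicate 3 and the YAP median -0.81 without NBD replicate 2. The S-phase median was -0.20, -0.08 and -0.22 without NBD replicate 3, control replicate 1 and control replicate 3. Over 15 alternatives adjusted p ran from 2.1e-14 to 0.763 for ribosomal protein, from 0.00261 to 0.647 for S-phase and from 8.8e-05 to 0.647 for YAP. With control replicate 3 as the only control library the NF-kB list turned to -0.28 and the YAP list to 0.23, and the calls of interferon at -0.05 (adjusted p = 0.649), hypoxia at -0.03 (0.690) and S-phase at 0.09 (0.338) were lost.

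**Figure D4:**
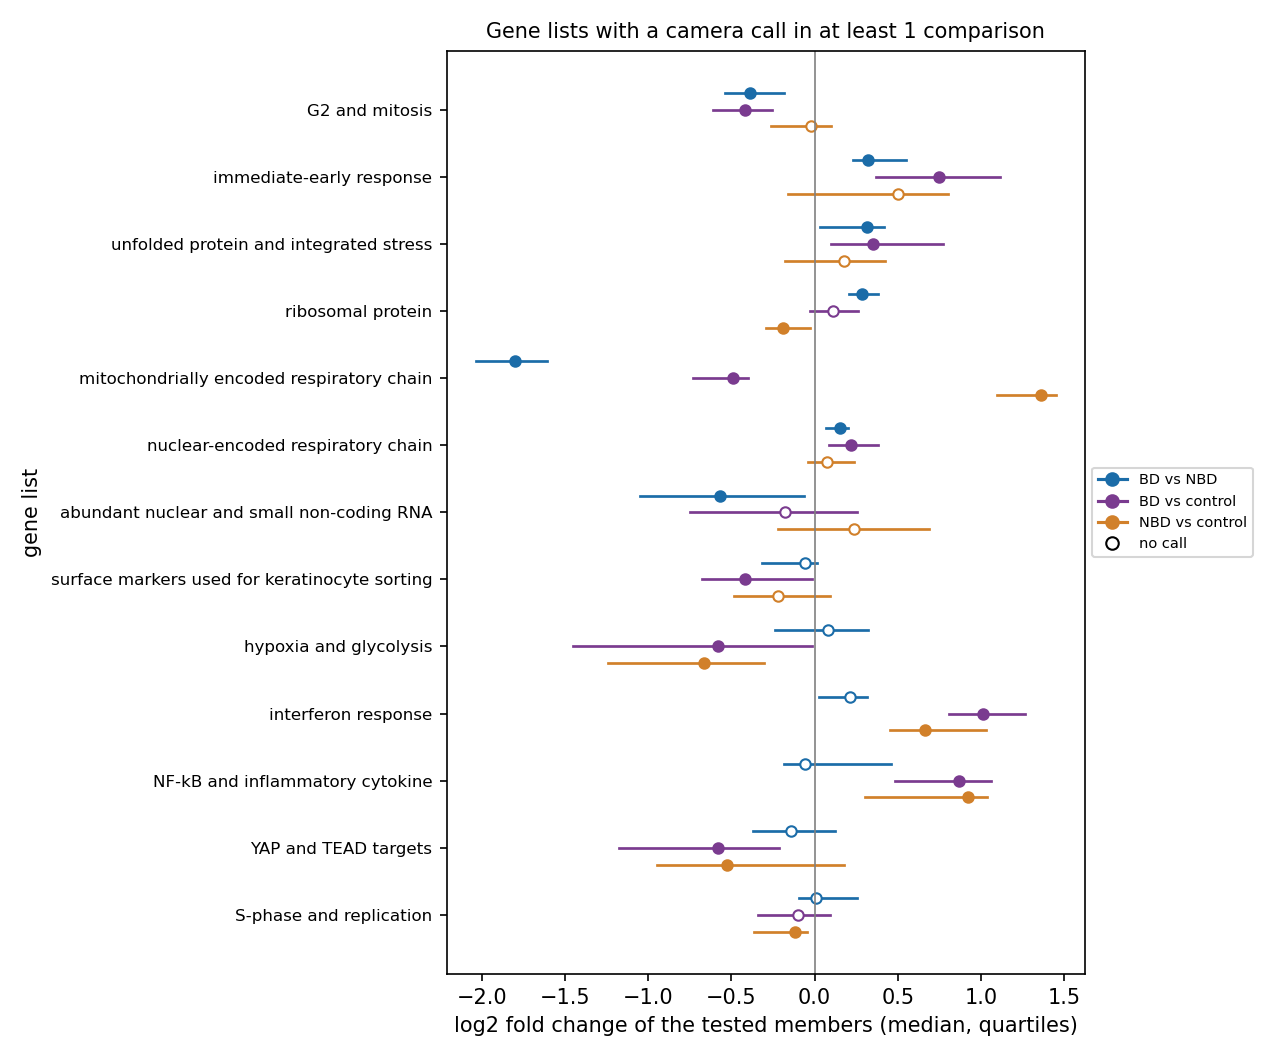
Median log2 fold change of the tested members of each list called in at least 1 of the 3 comparisons drawn, with bars from the lower to the upper quartile, filled where called by camera with the preset correlation and open where not. The mitochondrially encoded list lies at -1.80 in BD against NBD and 1.36 in NBD against control.

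For both subpopulations together against control, edgeR called 0 genes, with 2273 at an unadjusted p under 0.05 and 175 called by DESeq2, 14 higher and 161 lower. Without control replicate 3 the count was 4613 of 17755 genes tested, 2593 higher and 2020 lower. CA9 and BNIP3, chosen after their values were seen, were at -2.71 ± 0.51 and -3.19 ± 0.60 with all libraries, and fell by 3.17 ± 0.32 (edgeR, adjusted p = 1.3e-04) and 3.72 ± 0.23 (adjusted p = 9.2e-06) without control replicate 3, while over the alternatives adjusted p ran from 4.2e-09 and 6.4e-44 to 1.00 for both. Of the 11 fixed genes tested, 0 were called by edgeR with all libraries, at adjusted p from 0.332 to 0.863, and without control replicate 3 those called were KRT15, ITGA6, KRT5, TFRC and IVL. Of the lists, 8 were called: interferon response at 0.80, hypoxia and glycolysis at -0.57, NF-kB at 0.79, mitochondrially encoded respiratory chain at 0.43, YAP and TEAD targets at -0.54, immediate-early response at 0.59, G2 and mitosis at -0.22, and unfolded protein and integrated stress at 0.26. The mitochondrial median pools opposite list calls, at -0.49 in BD, where 3 of 13 members were above 0, and 1.36 in NBD against control. The mitosis median pools -0.42 in BD, where the list was called, and -0.02 in NBD, where it was not. By camera adjusted p of the 8 lists ran from 1.4e-10 to 0.0194, and from adjusted p = 0.600 to 0.706 with an estimated correlation. Adjusted over the list alone, 12 members of the hypoxia list and 3 of the mitochondrial list were called and 0 of the other 6. Without control replicate 3 these were 18 lower and 1 higher for hypoxia, 12 lower for YAP and 7 lower and 1 higher for mitosis. They were 23 higher for interferon, 18 higher for NF-kB, 20 higher and 2 lower for immediate-early, 8 higher and 1 lower for unfolded protein and 3 higher for the mitochondrial list. With all libraries the other 21 lists had adjusted p from 0.0504 to 0.984. Leaving out NBD replicate 2 or 3, or control replicate 1, raised the lists called to 13. The interferon, NF-kB and immediate-early medians without control replicate 3 were 1.73, 2.54 and 1.97, with 21, 17 and 18 members called higher over all genes (adjusted p = 0.117, 0.117 and 0.544 with an estimated correlation). The mitochondrial call was then lost at 0.43 (camera, adjusted p = 0.0501). Stress keratins and alarmins, S-phase and replication, and heat shock were at 0.24, -0.12 and -0.14 with all libraries. They were called at 2.19 (0.0164), -0.23 (0.0146) and -0.23 (0.0481) without control replicate 3, with adjusted p = 0.654 for each with an estimated correlation. Over the alternatives their adjusted p ran up to 0.988, 0.706 and 0.688. With control replicate 3 as the only control library the stress keratin list was called at -0.68 (1.2e-05) and the S-phase list at 0.14 (0.0243). Leaving out control replicates 1 and 2 in turn gave NF-kB medians of 0.39 and 0.41 and immediate-early medians of 0.21 and 0.26. With the replicate number as a block the NF-kB median was 1.33 and the immediate-early median 1.00. The unfolded protein median was 0.11 without control replicate 1, and the mitochondrial median 0.29 without NBD replicate 2. The calls of mitosis at -0.17 (0.0567) and of unfolded protein and integrated stress at 0.19 (0.0506) were lost without BD replicate 3 and BD replicate 2. Over 15 alternatives adjusted p of the 8 lists reached 0.600 to 0.799. With control replicate 3 as the only control library the immediate-early list turned to -0.40, the NF-kB list to -0.29 and the YAP list to 0.24, and the calls of interferon at 0.09 (adjusted p = 0.611), hypoxia at 0.09 (0.799), mitosis at 0.05 (0.799) and unfolded protein and integrated stress at 0.16 (0.177) were lost.

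The comparisons of BD and of NBD with control share their control libraries, so their fold changes are correlated with no effect at all. With all libraries, 0 genes were called by edgeR in both. The log2 fold changes correlated across genes at r = 0.728, against 0.510 in 20 simulations of unchanged groups, with a covariance of 0.330 against 0.123. The simulations gave every group the same spread, while the control libraries split, which can raise both values with no effect. These gaps therefore decide nothing about a change shared by BD and NBD. Without control replicate 3, 1696 genes were higher in both and 954 lower in both, with 3 in opposite directions, where independent lists would share 285 and 122. These calls set the sorted libraries against control replicates 1 and 2 alone, from which control replicate 3 lay apart as well. The excess over independent lists therefore cannot be told apart from the split among controls. The shared controls are too few to be split with 2 or more on each side. Without control replicate 3 the covariance was 1.86 against a simulated 0.146.

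Of the lists for immune cells, melanocytes and Langerhans cells, endothelium and erythroid cells, 3, 2, 2 and 0 members passed the filter, too few to test. The highest level of a member in any library was 6.86 CPM for the immune list, 4.30 CPM for the melanocyte and Langerhans cell list, 18.8 CPM for the endothelial list and 0.0787 CPM for the erythroid list. The cadherin gene CDH5 of the endothelial list and the receptor gene CD14 of the immune list, chosen after their values were seen, followed the split among controls. CDH5 stood at 1.07 and 0.785 CPM in control replicates 1 and 2, 16.6 CPM in control replicate 3 and 5.92 to 18.8 CPM in the sorted libraries. CD14 stood at 1.02, 0.617 and 6.33 CPM in the controls and 3.67 to 6.86 CPM in the sorted libraries. The list of fibroblast markers, with 5 tested members, was not called in the 4 comparisons, at adjusted p of 0.718, 0.177, 0.202 and 0.139 by camera. Its medians without control replicate 3 were -0.01 in BD against NBD, and 1.07, 1.61 and 1.17 in BD, NBD and both against control, without a call (adjusted p = 0.564, 0.131, 0.143 and 0.139, and from 0.0526 to 0.900 over the alternatives).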

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

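Control replicate 3 as the only control library, removal of mitochondrial rRNA genes and removal of a length trend were chosen after seeing the data. For BD against NBD, BD against control, NBD against control and both against control, edgeR called 131, 1162, 594 and 1250 genes with no filter, against 3, 0, 0 and 0. DESeq2 called 58, 167, 30 and 175. Limma-voom called 5 and 1 in the first and second of these comparisons. BD against NBD gave 5 genes with its 6 libraries alone. The cause was not tested. Leaving out 1 library in turn gave 0 to 16, 0 to 4317, 0 to 3228 and 0 to 4613 genes, and 6 to 12, 8 to 11, 7 to 15 and 9 to 13 lists against 7, 10, 7 and 8. It gave 0 to 2650 calls shared by BD against control and NBD against control.

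With an estimated correlation 1, 0, 0 and 0 lists were called. Among genes with a transcript length, 6 lists were called in BD against NBD before a length trend was removed and 4 after. The immediate-early list was not among the 6, with adjusted p = 0.144 by the list test before removal and 0.223 after. The unfolded protein and integrated stress list went from 0.32 (adjusted p = 0.0228) to 0.25 ± 0.06 (0.0729) and the abundant nuclear and small non-coding RNA list from -0.57 (0.0150) to -0.46 ± 0.25 (0.0507, SE over members), and both calls ended as the medians shrank. With control replicate 3 as the only control library, immediate-early response turned to -0.12 and NF-kB to -0.19 in BD against control, NF-kB to -0.28, YAP to 0.23 and immediate-early, uncalled with all libraries, to -0.57 in NBD against control, and immediate-early to -0.40, NF-kB to -0.29 and YAP to 0.24 for both. With their calls lost, hypoxia also changed sign to 0.12 in BD and 0.09 for both, YAP to 0.17 in BD, interferon to -0.05 and S-phase to 0.09 in NBD, and mitosis to 0.05 for both. That setting has 1 control library, assumed to vary as the other groups do, and its 0 called genes do not show that values did not differ. The cause was not tested.

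With the replicate number as a block 0 genes were called in BD against NBD, with MT-ND4 and MT-ATP6 at adjusted p = 0.0616 and MT-CYB at 0.0641 by edgeR. Libraries with the same number correlated at 0.0359 to 0.601 in their deviations, 6 of 9 pairs above 0.1, and 5 of 9 libraries correlated best with their own number in both other groups. Pairs with different numbers ran from -0.550 to 0.405. The numbers were not taken to pair samples, but an effect shared by libraries with the same number was not excluded. Over 18 alternatives the log2 fold change of MT-ND4 ran from -1.95 to -1.65 and its adjusted p from 3.4e-13 to 0.404, against 2.6e-12 to 0.404 for MT-ATP6 and 3.8e-10 to 0.459 for MT-CYB. In simulated data with the spread of the fit to all 9 libraries, which holds the split among controls, most 2-fold changes were not detected.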

Other observations

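The tests of reads taken by mitochondrial rRNA, of mitochondrial DNA, of short RNA loss, of mitochondrial transcripts of every kind, of a mislabelled library and of the share of cycling cells were chosen only after the result was seen. So were the genes named in the next paragraph and the counts of genes at or above the floor. The bounds of these tests were also set with values in view.

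Of the 49 genes that DESeq2 called lower in BD than in NBD, 5 are given here, with no test of a shared function: LUC7L3 at -1.60 ± 0.31 (adjusted p = 3.3e-04), PNN at -1.12 ± 0.24 (0.00270), the splicing factor genes SRSF5 at -0.81 ± 0.17 (0.00206) and SRSF11 at -0.84 ± 0.18 (0.00306), and PNISR at -1.01 ± 0.25 (0.0157). edgeR's quasi-likelihood test called none of these 5, at adjusted p from 0.258 to 0.388, and over the alternatives adjusted p ran from 1.7e-07 for LUC7L3, 0.0122 for PNISR and the DESeq2 value for the others to 1.00 for each. The BD and NBD libraries did not overlap for any of the 5, which chance gives for 10% of genes in a 3 against 3 design, in either direction. The 5 were picked from calls on these same libraries, so this separation adds no support. The small nucleolar RNA gene SNORD17 was at -1.86 ± 0.26 (edgeR, adjusted p = 0.0566, from 3.05e-10 to 0.549 over the alternatives). Of 64 small nucleolar RNA genes tested, 48 were below 0, at a median of -0.30.

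Mitochondrial mRNA was lower in BD, where mitochondrial rRNA took a smaller share of counts, by -7.44 percentage points (SE 1.63), which argues against reads taken by rRNA. Mitochondrial DNA in the NBD libraries would add the same number of reads per base to each gene, but the rise differed 181-fold between MT-CO3 and MT-ND6, and 87.6-fold with MT-CO1 against MT-ND6 after moving both by 2 standard errors. Loss of short RNA would spare long mRNAs, but the 5 longest had a median of -1.75 (SE 0.137 over genes). The mRNAs fell beyond the rRNAs by -1.40 (SE 0.257). In rRNA-depleted libraries the rRNA counts are what depletion left, so this gap cannot decide whether mitochondrial transcripts of every kind fell. The 10 mitochondrial tRNA genes tested were all below 0, at a median of -2.34. An earlier test, of reads shared with nuclear copies of these genes, was replaced after its result was seen: their median of -1.65 (SE 0.290) argued against a shift of reads to them. A difference in mitochondrial mRNA between the sorted cells may remain as a hypothesis, and the unrecorded assignment of RNA kits was not tested as such.

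Control replicate 3 resembled the sorted libraries more than the other controls at equal depth too, the correlations differing by -0.0123, which argues against depth. Whether it is a sorted library under a wrong label cannot be told apart. Its median log2 CPM of mitochondrial mRNA, 5.67, lies 0.495 outside the nearer range of BD (4.86 to 5.17) and NBD (6.73 to 7.30). Its small nucleolar RNA share of 0.509%, of which SNORD3A alone made up 0.494%, lies outside both as well (0.126 to 0.145% and 0.572 to 0.745%). Both values lie between the BD and NBD ranges. Its shares of mitochondrial mRNA and rRNA, 0.538% and 20.7%, instead lie within those of BD (0.413 to 0.547% and 17.3 to 22.3%). Its chi-square per degree of freedom against BD replicate 3 was 26.9, and that of BD replicate 2 was 27.4. Control replicates 1 and 2 might be a sub-line with other chromosome copy numbers: the variance over windows of 100 neighbouring genes, relative to shuffled genes, was 12.5 and 10.6, but NBD replicate 3 had 15.1, so this cannot be told apart. Of 122 genes at the floor in both, 10 were on chromosome X, a count with no share over all genes screened beside it, so it decides nothing. Of 30 genes on in both and at the floor in most others, 13 were also at 1 CPM or more in NBD replicate 2, unevenly, ELFN2 at 8.19 against 2.30 and 1.96 CPM and ADD2 at 1.61 against 61.2 and 59.0.

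The mitosis list kept a median of -0.42 after a trend with transcript length was removed, which argues against that trend as its whole cause. The ribosomal protein list kept 0.26, but this cannot decide. The lengths used, at a median of 1841.5 bases for that list, may not be those of the transcripts present. Trends with length also differed within groups. Spearman rho was 0.157, -0.209 and -0.123 in the BD libraries and 0.117, 0.0799 and -0.0932 in the NBD libraries, in replicate order. A smaller share of cycling cells in BD was taken to lower S-phase genes about as much as mitosis genes. The S-phase median was 0.00832, above that of the mitosis list (-0.39) by 0.398, beyond the SD of 0.297 over its 31 members. That SD is over genes that vary together (estimated correlation 0.321) and not over libraries, so the test cannot decide for or against this cause. Over 16 alternatives the S-phase median ran from -0.03 to 0.10, and whether G2 and mitosis alone differ was not tested. The bound of that test was reworded 3 times after its value was known: both first wordings and the present one count the value against the explanation, and the other, a median above 0 by 2 standard errors, left it open. Neither the mitosis nor the ribosomal list was called with an estimated correlation, and without NBD replicate 1 the ribosomal list was at 0.06 (camera, adjusted p = 0.461).

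Groups of 3 against 3 make 10 splits, too few for a share under 0.05. For genes, BD against NBD gave 3 and the highest other split 0 (1 of 10 as large), BD against control 0 and 0 (10 of 10), and NBD against control 0 and 722 (10 of 10). For lists these were 7 and 13 (9 of 10), 10 and 13 (3 of 10), and 7 and 14 (8 of 10). The number of lists called therefore does not set the real groups apart from wrong splits, and chance was not excluded for it. Among lists called in BD against NBD, the estimated correlation ran from -0.0481 for abundant nuclear and small non-coding RNA to 0.786 for ribosomal protein. For most of them the preset correlation was lower, and only the mitochondrially encoded list stayed called with the estimated one. For both subpopulations against control, fitted as 2 groups, 40 of 84 splits gave at least the 11 lists of the real one, up to 17, so chance was not excluded for lists. The real split gave 0 genes, which all 84 splits reach whatever the data, up to 2543, so the gene count decides nothing, as in the comparisons of BD and of NBD with control. The splits with 722 and 2543 genes set NBD replicate 2 with control replicates 1 and 2, which points to a structure of the samples.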
